A study of Neurospora crassa OR74A with 2 samples.

How the data were processed

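RNA-seq was done on 1 wild-type library (FGSC 2489) and 1 Δpp-1 library of Neurospora crassa, from conidia grown for 5 h at 30 °C. Per the labels' protocols, RNA was extracted with Trizol, mRNA was purified on oligo(dT) beads and fragmented with a zinc solution, cDNA was made with random primers, adapters were ligated, and fragments of a chosen size were taken from a gel and amplified by PCR. The kit steps described do not mark strand, so reads of overlapping genes on opposite strands are not told apart. TopHat and Cufflinks are named in the submitters' processing notes, without version or role. The genome build and annotation were not given in the sources used here.

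Each library came as 1 table of a gene identifier and a value. The values are RPKM per the file headers, that is, the authors divided reads by gene length and by a library total expressed in units of 1000000 reads. No further step of theirs is recorded in the sources used here. No columns of other samples were present. Each table had 8802 lines for 8564 genes. A total of 238 genes were listed more than once, with the same value each time, and every one of these was at 0 in exactly 1 library (126 in Δpp-1 and 112 in the wild type). Each gene was counted once. A further 116 genes listed once were at 0 in Δpp-1 alone and 134 in the wild type alone, and 559 were at 0 in both. An exact 0 in such a file can be a failed estimate. Genes at 0 are therefore said to be listed at 0, and no single fold is printed for them. In counts of genes past a threshold and in list medians they entered through the pseudocount given below.

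Identifiers were matched to NCBI RefSeq's gene table of assembly NC12, used only for symbols, gene spans and which genes neighbour each other, since the build of the files is not known. Of 8564 identifiers, 8087 matched a current locus tag and 151 an older one. The other 326 had no match, 48 of them because they shared 1 newer tag with another identifier. A symbol was found for 1097 genes and a span for 96.2%. No coordinates were used, and no GC content was analysed.

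The RPKM values were kept as deposited. Differences were computed as log2((Δpp-1 + 1)/(wild type + 1)), with a pseudocount of 1 RPKM. With 1 library per strain no test was possible. Genes were counted by a fixed rule of size, at least 2-fold higher or lower, over genes with at least 10 RPKM in the higher library. For each gene list with at least 3 members at a mean of at least 1 RPKM, the median log2 fold was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression. This percentile describes these libraries and is no test of the strains.

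The depth was read from the values. RPKM multiplied by annotated span in kilobases piled up at 0.254 in the wild type (22 genes, against at most 3 at shifted positions) and at 0.214 in Δpp-1 (25 genes against at most 4), which is what 1 read is worth. This gives library totals of 3935040 and 4681960 reads. Of 800 genes above 0 and under 1.5 RPKM in both libraries, 100 had a log2 ratio within 0.001 of 0.251, the log2 ratio of these steps, as genes with equal reads would have, and 0 lay as close to values 0.05 lower or higher. Whole reads per gene were not recovered for most genes, since spans hold introns and the annotation used by the authors is unknown. Counting intervals are exact (Clopper-Pearson) 95% intervals of the RPKM ratio, Δpp-1 over wild type, without a pseudocount. The median gene they are set against is on the scale with the pseudocount. The intervals use 50% of the reads that RPKM and span give, as a cautious figure, and cover counting error only. PCR copies without molecular identifiers are not independent molecules.

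The rule for the genes named was set before the data were examined, together with 13 gene lists given by symbol and locus tag. These were the MAK-2 cascade, the MAK-1 cascade, other cell fusion genes, the OS-2 cascade, pheromone and mating genes, the mating type A genes, G protein and cAMP signalling, conidiation and conidial genes, clock and light, chitin and glucan synthases, oxidative stress, nitrate and nitrogen use, and housekeeping genes. The rule took pp-1, every measured member of the first 6 lists, the 12 genes with the smallest and the 12 with the largest log2 folds among those with at least 10 RPKM in the higher library and above 0 in both, the next 8 in each direction with a named product, up to 5 genes in each direction listed at 0 in 1 library and at 10 RPKM or more in the other, up to 2 members with the smallest and 2 with the largest folds of each other list, and 5 genes on either side of pp-1. The gene table gives no product names, so "with a symbol" replaced "with a named product". For the same reason 26 lists defined by product words could not be applied, and 26 lists defined by gene symbols were written in their place after the files had been opened and before their folds were computed. The gene fl and 6 others outside the rule were named after their values were seen. The genes ste-50 and fks-1 were left out because the gene table gives their locus tags another symbol. ham-5 is covered by 2 older models that were kept apart. mfa-1 and pre-2 were not analysed here.

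Alternatives set before the data were examined were pseudocounts of 0.1 and 5, other filters on low values, thresholds of 1.5-fold and 4-fold, and scaling by the median, by the sum and by the upper quartile. Scaling by the reads in listed genes and leaving out genes listed at 0 were added after seeing the data. The steps were tested on simulated data for 8238 genes. Of 200 genes changed 4-fold in the simulated comparison, 100% of the higher and 100% of the lower ones were past 2-fold, as were 0 of 4497 unchanged genes. The simulated libraries in this comparison differed by counting noise only. The result therefore does not show how often unchanged genes pass 2-fold between unreplicated cultures. Of 200 unchanged lists of 10 genes 7% lay outside the central 95% of random lists, and of 50 lists shifted 2-fold higher 100% lay above it. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.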

Results

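Transcript levels were measured in Neurospora crassa, a filamentous ascomycete, in 1 library of the wild type (strain FGSC 2489) and 1 library of the Δpp-1 deletion strain. The pp-1 gene encodes a Ste12-type transcription factor. Both cultures were started from conidia, the asexual spores, and grown for 5 h at 30 °C. At this age germinated conidia (germlings) of the wild type fuse with one another, and fusion in these cultures was not measured here. Values were available for 8564 genes in each library as RPKM (reads per kilobase of gene, scaled to a library total of 1000000), of which 7517 were above 0 in both. The median gene stood at 11.95 RPKM in the wild type and 9.84 RPKM in Δpp-1, and the upper quartiles were 32.2 and 26.9 RPKM. The spacing of the low values put the library total used for the scaling at 3935040 reads for the wild type and 4681960 for Δpp-1. With 1 library per strain, no difference below has a replicate check, no p-value is given, and each value describes these 2 libraries. Unless stated otherwise, fold differences are on the log2(RPKM + 1) scale, which understates those of low genes.

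The deleted gene was compared first. The pp-1 transcript (NCU00340) stood at 83.8 RPKM in the wild type and at 1.69 RPKM in Δpp-1, a ratio of 49.5-fold. The log2 fold was -4.98, and the 95% counting interval of the log2 ratio ran from -6.41 to -4.94. The low value was on the side its label calls for. The gene next to pp-1 on one side, NCU00343, was at 0.889 RPKM in the wild type and listed at 0 in Δpp-1, and NCU00339 on the other side was not analysed here. The remaining genes among the 5 on either side of pp-1 in assembly NC12 had log2 folds from -0.91 (NCU00346) to 0.21 (NCU00338), and none was 2-fold higher or lower.

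The next comparison asked which transcripts differed between germlings with and without PP-1. Genes of known function were among those with the largest differences in both directions. Prm1 (NCU09337), a membrane protein gene that acts in plasma membrane fusion, stood at 43.4 RPKM in the wild type and 0.512 RPKM in Δpp-1. The cell wall protein gene acw-10 (NCU03013) stood at 368 and 24.7 RPKM, and gh61-2 (NCU07760), of a family of polysaccharide-degrading enzymes, at 55.7 and 1.06 RPKM. In the other direction, the pheromone precursor gene ccg-4 (NCU02500) stood at 48.6 RPKM in the wild type and 642 RPKM in Δpp-1, adh-1 (NCU01754), an alcohol dehydrogenase gene, at 27.3 and 448 RPKM, and cfp (NCU02193), which encodes pyruvate decarboxylase, at 161 and 1644 RPKM.

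Of 4831 genes with at least 10 RPKM in the higher library, 132 were at least 2-fold higher and 337 at least 2-fold lower in Δpp-1, so that 71.9% of the genes past 2-fold were lower. Genes listed at 0 in 1 library are among them, 1 higher and 13 lower. The split between higher and lower depended on how the libraries were scaled to each other. The median gene had a log2 fold of -0.28 in the values as deposited. Each library was then scaled by its median over genes with a mean of at least 10 RPKM. After this the counts were 210 higher and 219 lower (51.0% lower). With both libraries rescaled to a sum of 1000000 they were 288 and 197 (40.6% lower). Medians of gene lists with a percentile are therefore also given relative to the median of the 6885 genes with a mean of at least 1 RPKM (-0.25), called all genes below, and single genes in part relative to the median gene (-0.28). The counting interval lay beyond the median gene for 130 of 130 higher genes and 312 of 315 lower genes that have an annotated span. These genes were chosen by size from the same values, so this was largely fixed in advance and lends them no support.

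Among genes with at least 10 RPKM in the higher library and above 0 in both, the 12 with the smallest log2 folds were pp-1 itself and 11 genes without a symbol. NCU04496 stood at 377 RPKM in the wild type and 0.386 RPKM in Δpp-1, NCU01380 at 413 and 0.688 RPKM, NCU04527 at 249 and 0.983 RPKM, and NCU07802 at 148 and 0.405 RPKM. The others of this group were NCU09562 (501 and 5.03 RPKM), NCU11172, NCU01697, NCU10610, NCU09848, NCU02613 and NCU08433. The next 8 with a symbol were Prm1, gh61-2, acw-10, gh61-9, gh10-3, gh28-1, xr and ada-1. Of these, gh61-9 (NCU05969) stood at 47.8 and 2.71 RPKM, gh28-1 (NCU02369) at 18.3 and 1.56 RPKM, and the transcription factor gene ada-1 (NCU00499) at 45.4 and 6.55 RPKM. A further 13 genes had at least 10 RPKM in the wild type and were listed at 0 in Δpp-1. The highest of these were NCU00995 at 274 RPKM, NCU05712 at 39.1 RPKM, NCU05629 at 36.9 RPKM, NCU03294 at 22.3 RPKM and NCU03247 at 17.8 RPKM, and 6 of the 13 were listed more than once in the files.

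With the same limits, the 12 genes with the largest log2 folds were adh-1, ccg-4, ncw-3, cfp and 8 genes without a symbol. NCU05498 stood at 8.64 RPKM in the wild type and 232 RPKM in Δpp-1, NCU05338 at 52.3 and 783 RPKM, NCU04276 at 125 and 1385 RPKM, and NCU09174 at 2.76 and 64.1 RPKM. The others without a symbol were NCU04169, NCU08330, NCU00175 and NCU06804. The cell wall protein gene ncw-3 (NCU07817) stood at 8.59 and 98.1 RPKM. The next 8 with a symbol were ccg-14, con-10, pho-5, aod-1, al-1, mig-4, cbs-1 and pdx-4. The alternative oxidase gene aod-1 (NCU07953) stood at 67.7 and 370 RPKM, and the clock-controlled gene ccg-14 (NCU07787) at 8.49 and 59.7 RPKM. NCU09528 was listed at 0 in the wild type and at 16.3 RPKM in Δpp-1.

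**Figure D1:**
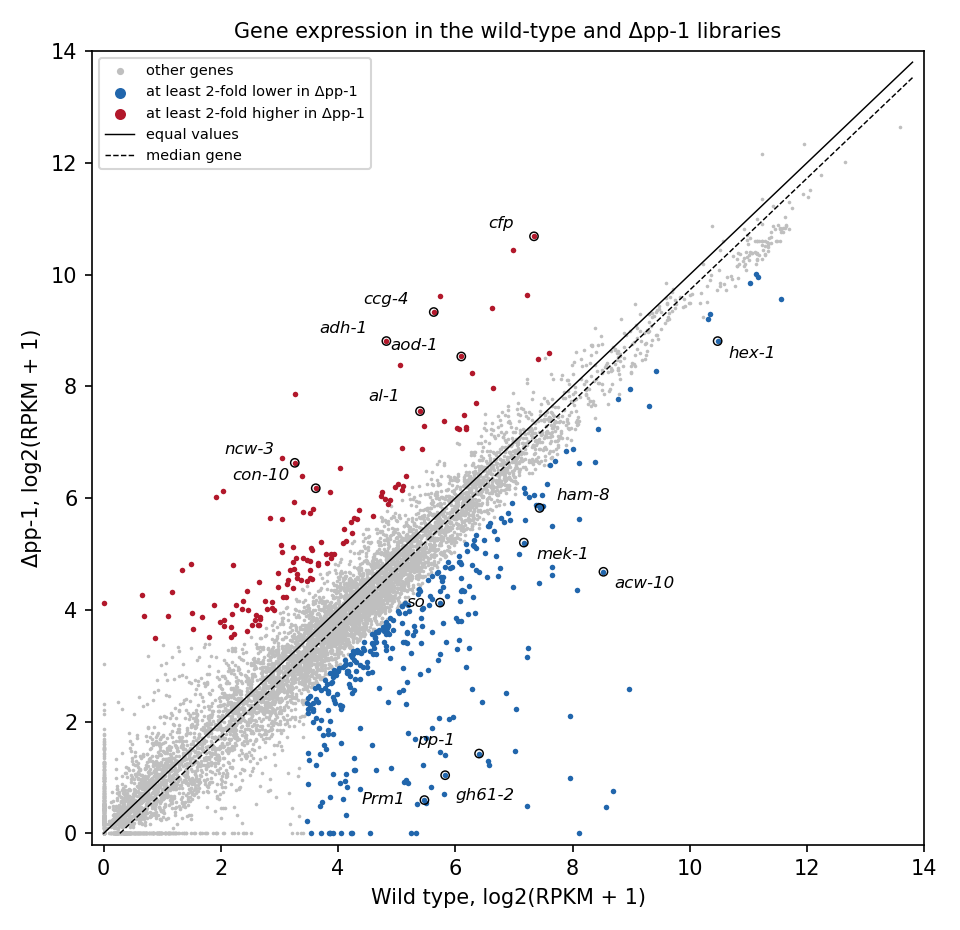
Each point is 1 of 8564 genes, with log2(RPKM + 1) in the wild-type library on the horizontal axis and in the Δpp-1 library on the vertical axis. Blue points are the 337 genes at least 2-fold lower and red points the 132 at least 2-fold higher in Δpp-1, the solid line marks equal values and the dashed line the median gene at a log2 fold of -0.28. The pp-1 transcript lies far below both lines, as do Prm1 and gh61-2, and cfp, ccg-4 and adh-1 lie far above them.

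Genes of cell fusion and its signalling were grouped in lists fixed beforehand. The list of the MAK-1 cell wall integrity cascade, a MAP kinase pathway needed for germling fusion, had a lower median in Δpp-1 than random lists. As set beforehand, this list also held the fusion genes ham-6, ham-7 and ham-8 and the transcription factor gene adv-1. Of its 9 measured members 5 were at least 2-fold lower and none was 2-fold higher. The kinase gene mek-1 (NCU06419) stood at 143 RPKM in the wild type and 35.8 RPKM in Δpp-1, and the fusion genes ham-6 (NCU02767) at 74.2 and 20.6 RPKM, ham-8 (NCU02811) at 172 and 55.6 RPKM and ham-7 (NCU00881) at 145 and 67.3 RPKM. The transcription factor gene adv-1 (NCU07392) stood at 95.6 and 45.7 RPKM, and mak-1 (NCU11376) had a log2 fold of -0.68. For rho-1, wsc-1 and mik-1 the log2 folds were -0.14, -0.09 and 0.13. The list's median log2 fold was -1.05, or -0.80 relative to all genes, at percentile 0.01 of 10000 random lists of the same size and expression. Relative to the median gene, 3 of the 9 were still at least 2-fold lower, with values of -1.69 for mek-1, -1.52 for ham-6 and -1.34 for ham-8. In the same Δpp-1 library the conidial markers con-10, con-6 and eas were 6.32-fold, 3.36-fold and 3.07-fold higher as ratios of RPKM. The ratios of ccg-1 (0.92), con-8 (0.81), fl (0.94) and acon-3 (0.36), from the same conidial list, were below 1 in the values as deposited. Relative to the median gene, their log2 folds were 0.17, 0.05, 0.21 and -0.49. The gene fl was named after its value was seen.

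The 3 measured kinase genes of the MAK-2 cascade, the MAP kinase pathway upstream of PP-1, were not 2-fold higher or lower. The log2 folds were -0.37 for mek-2 (NCU04612), -0.12 for mak-2 (NCU02393) and 0.01 for nrc-1 (NCU06182), and the median, 0.13 above that of all genes, was at percentile 71.3. The scaffold protein gene ham-5 is covered in the files by a pair of separate older gene models, which entered no list: NCU11226 stood at 38.7 RPKM in the wild type and 11.4 RPKM in Δpp-1, and NCU11227 at 20.5 and 6.84 RPKM.

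Of 15 other cell fusion genes, 5 were at least 2-fold lower and none 2-fold higher. They were Prm1, so (NCU02794, 52.4 and 16.5 RPKM), NCU07192 (169 and 57.6 RPKM), the NADPH oxidase gene nox-1 (NCU02110, 89.6 and 31.4 RPKM) and ham-9 (NCU07389, 58.7 and 25.9 RPKM). Relative to the median gene, 4 of the 15 were at least 2-fold lower, without ham-9, and 8 lay below it. The other members, nor-1, NCU10518, NCU07191, NCU06593, ham-3, cdc42, ham-4, rac-1, ham-10 and ham-2, had log2 folds from -0.76 (nor-1) to -0.05 (ham-2). The median log2 fold of the list was -0.47, or -0.22 relative to all genes, at percentile 3.77, inside the central 95% of the random lists.

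The 4 genes of the OS-2 osmosensing cascade were between 2-fold lower and 2-fold higher, from -0.23 for os-5 (NCU00587) through 0.00 for os-2 (NCU07024) and 0.11 for os-1 (NCU02815) to 0.68 for os-4 (NCU03071), and the median, 0.30 above that of all genes, was at percentile 89.6. Among pheromone genes ccg-4 was higher, as given above, and the receptor gene pre-1 (NCU00138) stood at 1.56 and 2.15 RPKM. The mating type gene matA-1 (NCU01958) stood at 4.06 RPKM in the wild type and 4.85 RPKM in Δpp-1. matA-3 (NCU01960) was at 0.521 and 0.329 RPKM, and matA-2 (NCU01959) was listed at 0 in the wild type and at 0.294 RPKM in Δpp-1. These 2 lists had under 3 measured members and no percentile.

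**Figure D2:**
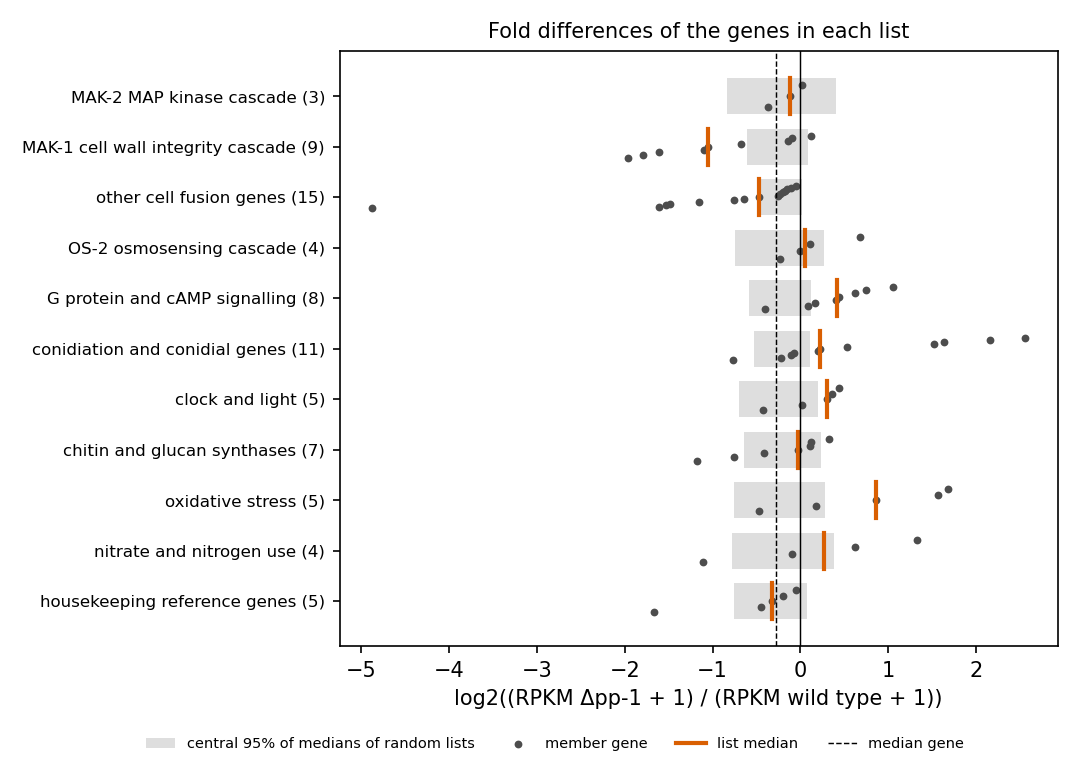
Points are the log2 folds of the measured members of each of 11 gene lists, with the number of members in brackets, and orange bars are the list medians. Grey bands span the central 95% of medians of 10000 random lists matched on expression, and the dashed line is the median gene at -0.28. The MAK-1 cascade median (-1.05) lies below its band, and the medians for G protein and cAMP signalling (0.42), conidial genes (0.23), clock and light (0.30) and oxidative stress (0.86) lie above theirs.

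Several other lists stood higher in Δpp-1 than random lists. Of 11 measured genes of conidiation and conidia, which also mark conidia and aerial hyphae as other cell types in the culture, 4 were at least 2-fold higher and none 2-fold lower. The conidial gene con-10 (NCU07325) stood at 11.3 RPKM in the wild type and 71.3 RPKM in Δpp-1, and the carotenoid pathway gene al-1 (NCU00552) at 41.1 and 187 RPKM. The other members past 2-fold, named after their values were seen, were con-6 (NCU08769, 8.78 and 29.5 RPKM) and the hydrophobin gene eas (NCU08457, 9.55 and 29.3 RPKM). The lowest members were the regulator acon-3 (NCU07617, 1.83 and 0.668 RPKM) and con-8 (NCU10997, 3.57 and 2.91 RPKM), and ccg-1 (NCU03753), also named after its value was seen, stood at 14.3 and 13.2 RPKM. The list's median was 0.23, or 0.48 relative to all genes, at percentile 99.5. Without members under a mean of 10 RPKM it was 1.03, since this leaves out low members such as acon-3 and con-8. Of the 11 genes, 10 lay above the median gene and 1, acon-3, below it. The rise past 2-fold of con-10, con-6, eas and al-1, not reached by acon-3, con-8 and ccg-1, was in the library that also differed in other lists. These were the fusion genes above and the lists of oxidative stress, G protein signalling and clock genes below.

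Among 5 genes of oxidative stress defence, the catalase genes cat-3 (NCU00355, 10.6 and 33.4 RPKM) and cat-1 (NCU08791, 1.55 and 7.19 RPKM) were at least 2-fold higher in Δpp-1, the library in which con-10, con-6, eas and al-1 were also past 2-fold. cat-2 (NCU05770), named after its value was seen, stood at 2.83 and 5.96 RPKM. The superoxide dismutase genes sod-1 and sod-2 had log2 folds of -0.47 and 0.18. Relative to the median gene, all 3 catalase genes were at least 2-fold higher. The list's median was 0.86, or 1.11 relative to all genes, at percentile 99.95, and without members under a mean of 10 RPKM it was 0.18 at percentile 94.7.

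Of 8 genes of G protein and cAMP signalling, 1 was at least 2-fold higher, the Gα gene gna-2 (NCU06729), at 33.1 RPKM in the wild type and 69.7 RPKM in Δpp-1. The Gα gene gna-1 (NCU06493) stood at 118 and 199 RPKM, and the lowest members were pkac-1 and mcb with log2 folds of -0.40 and 0.09. The list's median was 0.42, or 0.67 relative to all genes, at percentile 99.9. The 5 genes of the circadian clock and light sensing had a median of 0.30, or 0.55 relative to all genes, at percentile 98.8 and none was past 2-fold. Their log2 folds were 0.45 for frq (NCU02265), 0.36 for wc-1, 0.02 for wc-2 and -0.43 for fwd-1, and leaving out 1 member brought the percentile as low as 94.7.

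The other 3 lists fixed beforehand lay inside the central 95% of random lists. Among nitrogen genes, the nitrate reductase gene nit-3 (NCU05298) stood at 70.3 RPKM in the wild type and 178 RPKM in Δpp-1, and nit-6, a nitrite reductase gene, had a log2 fold of 0.62. The regulator nit-2 (NCU09068) stood at 66.1 and 30.2 RPKM and nit-4 at 3.87 and 3.56 RPKM. This list had a median of 0.26, or 0.51 relative to all genes, at percentile 95.2, and without members under a mean of 10 RPKM a median of 0.62 at percentile 98.4. Of 7 genes in the list of chitin and glucan synthases, chs-3 (NCU04251) was at least 2-fold lower, at 60.6 and 26.3 RPKM, and NCU05239 had a log2 fold of -0.76. The highest, chs-5 and chs-4, were at 0.32 and 0.12, and the list, with a median 0.22 above that of all genes, was at percentile 81.7. Of 5 housekeeping genes, hex-1 (NCU08332), which encodes the protein of the Woronin body that plugs septal pores, was at least 2-fold lower, at 1422 and 448 RPKM. pma-1 had a log2 fold of -0.45 and gpd-1 of -0.19. For act it was -0.05, which is 0.23 above the median gene, so the side on which these last 2 lie depends on the scaling. This list had a median of -0.33, or -0.08 relative to all genes, at percentile 66.0.

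In all, 5 of the 11 lists fixed beforehand that had a percentile lay outside the central 95% of random lists, where 0.55 would be expected by chance. Members of a list that vary together widen the spread of its median, which the random lists do not allow for. Across the 4831 genes, which are not independent replicates, log2 values in the 2 libraries had a Pearson r of 0.886 and a Spearman rho of 0.863, and 95% of log2 folds lay between -1.83 and 1.07. The log2 fold had a Spearman rho of 0.01 with mean RPKM and 0.05 with annotated gene span, over 4771 genes.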

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

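The scaling by reads in listed genes and the counts without genes listed at 0 were chosen after seeing the data; the other alternatives were set before. No paired analysis was possible because each strain had 1 library, and for the same reason no replicate could be left out. Against 132 higher and 337 lower genes in Δpp-1, the counts were 210 and 219 with median scaling, 288 and 197 with both libraries at a sum of 1000000, 200 and 225 with upper-quartile scaling, and 267 and 195 with scaling by reads in listed genes. Each of these raises Δpp-1 relative to the wild type. They were 252 and 521 both with no filter and with at least 1 RPKM, 67 and 179 with at least 30 RPKM, 295 and 1125 at 1.5-fold, and 39 and 113 at 4-fold, where more or fewer genes can pass by construction. With pseudocounts of 0.1 and 5, and without genes listed at 0 (131 and 324), they stayed within 1.5 times. The log2 fold of pp-1 was -3.73 with a pseudocount of 5, which shrinks low values. With the sum at 1000000 and with scaling by reads, list medians shifted upward, to -0.66 and -0.68 for the MAK-1 cascade, -0.078 and -0.099 for other fusion genes, 0.82 and 0.78 for G protein and cAMP signalling, and 0.63 and 0.60 for conidial genes. Restricted to a mean of at least 10 RPKM, the median was 1.03 for conidial genes and 0.18 for oxidative stress, since this leaves out members. No list outside the central 95% of random lists changed the sign of its median under these alternatives. With 1 member left out, the median of the DNA repair list, near 0, reached -0.0029. The depth limits genes of a few RPKM most, since few reads lie behind them.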

Other observations

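The tests of explanations in this part were chosen after the results were seen, as were the lists described first, whose members were picked by symbol before their folds were computed. Of 26 such lists, 4 had a median outside the central 95% of random lists, where 1.3 would be expected by chance, and the other 22 lay between percentiles 2.6 and 94.8. The list of cytosolic ribosomal protein genes had a lower median in Δpp-1 than random lists, with a median log2 fold of -0.74, or -0.49 relative to all genes (percentile 1.33). All 9 members lay below the median gene, and 1, crp-15 (NCU00258), was at least 2-fold lower, at 2290 RPKM in the wild type and 991 RPKM in Δpp-1. Members were found by symbol, so genes of this class without a matching symbol were not in the list. Among genes with a mean of at least 10 RPKM the percentile was 4.01. Of 17 genes of the tricarboxylic acid cycle 16 lay below the median gene, with tca-17 (NCU00720) at 78.8 and 34.3 RPKM and tca-3 (NCU02366) at 506 and 247 RPKM (list percentile 2.6). None of the 17 was 2-fold lower relative to the median gene, and the list was at percentile 1.64 among genes with a mean of at least 10 RPKM and 2.04 with a pseudocount of 5. Genes of DNA repair stood higher relative to all genes by 0.25 (percentile 98.8), with mus-18 (NCU08850) at 6.32 and 15.3 RPKM. Among genes with a mean of at least 10 RPKM this list was at percentile 95.5. Clock-controlled genes were at percentile 98.9, with 3 of 9 at least 2-fold higher, among them ccg-4 and ccg-14, and leaving out 1 member brought the percentile as low as 97.4. The list shares ccg-4 with the pheromone list and ccg-1 with the conidial list. Genes of phosphate acquisition were at percentile 97.8, but at 92.7 with no filter and as low as 82.4 with 1 member left out.

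Among enzymes and proteins of polysaccharides and the cell wall, single genes moved far while list medians did not. Of 52 measured glycoside hydrolase and related genes 11 were at least 2-fold lower in Δpp-1 and none was 2-fold higher, and the median was at percentile 54.3. Besides gh61-2 these included gh61-7 (NCU00836), at 17.6 RPKM in the wild type and listed at 0 in Δpp-1. Of 17 cell wall protein genes 4 were at least 2-fold lower and 2 higher. ncw-1 (NCU05137) stood at 24.99 and 5.09 RPKM, and acw-9 (NCU06185), named after its value was seen, at 3012 and 760 RPKM, against ncw-3 in the other direction. The other of the 2 higher, ncw-5 (NCU00716), was listed at 0 in the wild type and at 3.38 RPKM in Δpp-1. The glutamine synthetase gene gln-2 (NCU04856), also named after its value was seen, stood at 81.0 and 207 RPKM, in the same direction as nit-3. Among 112 matched genes at least 4-fold lower, some of them listed at 0 in Δpp-1, 11 pairs lay at most 2 genes apart. Distances were counted over matched genes only, in their order in assembly NC12. In 10000 random draws of as many genes from the 4771 matched genes with at least 10 RPKM, the number of such pairs had a median of 3, a central 95% of 0 to 7 and a maximum of 12. Among 39 genes at least 4-fold higher there was 1 pair, and the draws had a central 95% of 0 to 2 and a maximum of 5.

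More genes were lower than higher in Δpp-1, with 71.9% of the genes past 2-fold on the lower side. A few abundant listed genes taking more of the summed RPKM in Δpp-1 is argued against. The share of the 10 most abundant genes in the summed RPKM differed by -0.11 percentage points (8.63% in Δpp-1 and 8.74% in the wild type). Transcripts outside the listed genes do not enter this share, so a larger part taken by those could not be seen. RPKM is per kilobase, so this share does not show what part of the reads the abundant genes took. With both libraries scaled to the same reads in listed genes, the lower side held 42.2%, but scaling moves all genes by about the same amount and lowers this share whatever the source, so the library totals the authors divided by cannot be told apart from other sources of a common shift. RPKM times span added up to 130% of the implied total in the wild type and 100.3% in Δpp-1, as upper figures, since spans hold introns. The same spans served both libraries, so introns give no ready reason for the gap between these figures. Relative to the reads in listed genes, the total divided by was thus smaller in the wild type. A change in total mRNA per cell was not measured, and values scaled to a library total cannot show one. The source of the shift stays open.

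The MAK-1 cascade list had a lower median in Δpp-1 than random lists, with 5 of 9 members at least 2-fold lower, and 3 of 9 relative to the median gene. The 5 were mek-1, the fusion genes ham-6, ham-7 and ham-8, and adv-1. The log2 folds of mak-1, rho-1, wsc-1 and mik-1 were -0.68, -0.14, -0.09 and 0.13. The low median thus rests in part on the placing of the ham genes and adv-1 in this list. Scaling is argued against as the whole source, since the list's median was still -0.68 with both libraries scaled to the same reads in listed genes, against -1.05 as deposited. Counting error is argued against as well, because 6 of the 9 members had counting intervals wholly below the median gene. In the Δpp-1 library the conidial transcripts con-10, con-6 and eas were also at least 2-fold higher. For ccg-1 and con-8 the log2 folds relative to the median gene were 0.17 and 0.05. With 1 library per strain, another mix of cells or another difference between the cultures cannot be told apart from the deletion. A hypothesis that remains open is that PP-1 may be needed, directly or indirectly, for the expression of some genes of this list, such as mek-1, ham-6 and ham-8.

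The list of conidial genes had a higher median in Δpp-1 than random lists, with 4 of 11 members at least 2-fold higher. A larger share of ungerminated conidia in that culture would raise conidial transcripts together. The 4 such transcripts with at least 10 RPKM were con-6, con-10, eas and ccg-1. Of these, only 1, ccg-1, had a counting interval (log2 ratio -1.02 to 0.78) wholly below that of con-10 (1.96 to 3.47). Below the 10 RPKM limit, con-8 (3.57 and 2.91 RPKM) also had an interval wholly below that of con-10 (-1.53 to 1.03). The outcome thus turned on this limit, and a larger share of conidia could be neither excluded nor favoured. A difference between the 2 cultures other than the deletion cannot be told apart from it with 1 library per strain. An effect of the deletion on conidial genes may also contribute, and it was not tested.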
